A study of Homo sapiens with 8 samples.

How the data were processed

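Messenger RNA of the CUTLL1 T-cell acute lymphoblastic leukemia line was measured on 8 Affymetrix GeneChip arrays, 2 for each of 4 treatments of 48 h: PF-03084014 or dexamethasone at 1 microM, both compounds together, and DMSO as vehicle. Per the labels, biotinylated cRNA was made from 200 ng of total RNA with an Affymetrix kit for amplification from the 3 prime end. The values the authors deposited are probe-set intensities on a linear scale for 54675 probe sets. The summarisation software, the normalization and the background step behind them are not given in the sources used here. Array medians lay between 61.8 and 63.9 except for 76.3 on the second combination array, 2% trimmed means lay between 425 and 437, and the smallest value was 1 on every array, so the values were on a common scale but were not quantile normalized.

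Intensities below 16 were set to 16 and the values converted to log2. Between 13.2% and 15.2% of probe sets per array were at or below that floor, and the median of 27 bacterial control probe sets not spiked into the samples was 18.6 to 23.4. Of the probe sets, 42898 carried a gene in the annotation supplied and 11777 did not. The 1801 that listed several genes were left out, and 41097 were used. Each of 19775 genes was represented by the probe set with the highest mean over the 8 arrays, with no filter on dim genes. Genes are given by symbol, and genome positions were not used here. Intensity over background and the 2 arrays per group set the precision, which was a median standard error of 0.178 log2 units for a difference between groups.

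Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 fit of all 8 arrays, a mean per group, 4 residual degrees of freedom and eBayes with an intensity trend, which added a median of 1.36 prior degrees of freedom. The contrasts were each treatment against DMSO, the combination against each single compound, and the interaction of the compounds. A gene was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes of a contrast. Values after a plus-minus sign are standard errors of the fit unless a standard deviation is named. They pool 1 spread over all groups, so those of contrasts with the combination, whose arrays varied more, tend to be too small. The 26 gene lists were tested with limma's camera with its preset inter-gene correlation of 0.01, adjusted over 156 list and contrast pairs, and again with an estimated correlation. With the estimate the test refers to 4 degrees of freedom, and no list was called in any contrast: the lowest adjusted p was 0.193. The directional test fry, which asks whether the genes of a list move on balance one way, called 11 lists for PF-03084014, 8 for dexamethasone and 14 for the combination, each against DMSO, 12 for the combination against dexamethasone, 12 against PF-03084014 and 2 in the interaction, at an adjusted p under 0.05.

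The lists were NOTCH targets, glucocorticoid receptor targets, metallothioneins, ribosome biogenesis, purine, pyrimidine and folate synthesis, amino acid and polyamine metabolism, aminoacyl-tRNA synthetases, glycolysis, cholesterol synthesis, DNA replication and G1/S, mitosis and G2/M, G1 cyclins with CDKs and CDK inhibitors, survival and death members of the BCL2 family, T cell receptor and thymocyte genes, FOXO targets and quiescence, type I interferon response, unfolded protein and integrated stress response, NF-kappaB targets, autophagy and lysosome, cytosolic ribosomal proteins, the mitochondrial respiratory chain, and markers of B-lineage, myeloid, erythroid and megakaryocyte, and epithelial and stromal cells. Some list members, such as PER1 and BIRC3, are not analysed here. Some genes belong to several lists, for example BCL2L11, PIK3IP1, IL7R and PTCRA. The genes named were, for each treatment against DMSO, the 8 largest rises and 8 largest falls among called genes whose treated arrays both lay beyond both control arrays, the 5 largest of each for the other contrasts, a set named beforehand (NR3C1, HES1, HES4, DTX1, NRARP, NOTCH3, NOTCH1, PTCRA, MYC, IL7R, BCL2L11, BCL2, MCL1, TSC22D3, FKBP5, ZBTB16, PER1, DDIT4 and KLF4), and from each list the members that rose and fell most. If no member was called, the one with the smallest p was named.

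The contrasts, floor, lists, naming rule and the alternatives to be tried were chosen before the data were examined. A floor of 64, a minimum mean intensity of 100, and quantile normalization without the second combination array were chosen after the values were seen. The other settings tried were quantile normalization, a shift of all arrays to 1 median, a floor of 32, a pseudocount of 16, leaving out genes below the median intensity, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, fits without trend or with robust estimation, only the groups compared, array weights, a replicate block, and each array left out in turn. The fit was tested on simulated data of the same size: it called 28.4% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 11 of 19545 unchanged genes. The changed genes were drawn from those with a mean DMSO intensity above 100, and each gene had the same simulated spread in all groups. These rates therefore do not cover dimmer genes or groups of unequal spread. Overlap between contrasts that share the DMSO arrays was set beside 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.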

Results

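The experiment measured messenger RNA in CUTLL1, a human T-cell acute lymphoblastic leukemia line with an activated NOTCH1 pathway, after 48 h of treatment. PF-03084014 is a gamma-secretase inhibitor, which blocks the cleavage that activates NOTCH receptors, and dexamethasone is a synthetic glucocorticoid. The 4 groups were DMSO vehicle, 1 microM PF-03084014, 1 microM dexamethasone and both compounds at 1 microM each (the combination), with 2 arrays per group. Each of the 8 arrays gave intensities for 54675 probe sets, from which 19775 genes were tested. Median intensity was 63.6 and 63.5 on the DMSO arrays, 63.3 and 63.9 on the PF-03084014 arrays, 63.4 and 61.8 on the dexamethasone arrays, and 63.4 and 76.3 on the combination arrays. The second combination array therefore stood apart: 43.9% of its probe sets exceeded an intensity of 100, against 40.4% to 41.0% on the other arrays. The spiked bacterial control bioB read 453 to 535 on the arrays with PF-03084014, alone or combined, and 609 to 721 on the others. The control bioC read 1556 to 1788 against 1831 to 2098, while bioDn and creX overlapped. The cause was not tested. Replicate arrays correlated across genes with r = 0.991 for DMSO, 0.993 for PF-03084014, 0.992 for dexamethasone and 0.980 for the combination, in which 1802 genes lay at least 2-fold apart. The labels call the arrays of a group the first and second replica and do not say whether these came from separate cultures, so the p-values measure only the spread between these samples. The small number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.178. That error pools 1 spread over all groups. The SD of the log2 difference between replicates was 0.548 for the combination and 0.325 to 0.361 for the other groups. Standard errors and p-values of contrasts with the combination therefore tend to be too small.

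**Figure D1:**
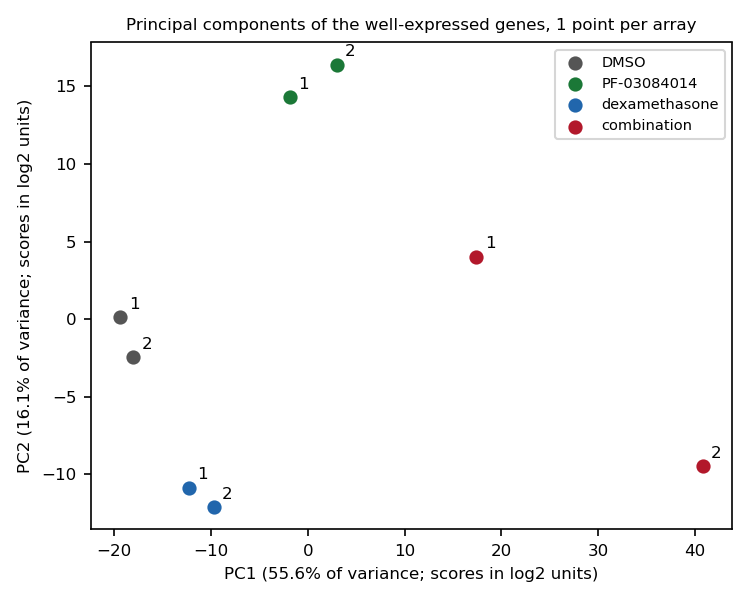
First and second principal component scores (log2 units) of the 8 arrays over 10692 genes with a mean intensity above 100, with the replicate number beside each point. The first component held 55.6% of the variance, and on it the combination arrays scored 17.4 and 40.8, to the right of all other arrays.

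The first comparison asked what NOTCH inhibition alone changed, and NOTCH targets were among its largest effects. NRARP, a feedback inhibitor of NOTCH signalling, fell by 2.66 on the log2 scale with PF-03084014, from 12.51 ± 0.15 to 9.85 ± 0.056 log2 intensity (mean ± SD, n = 2). The ubiquitin ligase gene DTX1 changed by -2.18 ± 0.083 log2 units (estimate ± SE, limma adjusted p = 0.00709), and the transcriptional repressors HES1 and HEY1 by -1.74 ± 0.15 and -2.28 ± 0.15. PTCRA, which encodes the invariant chain of the pre-T-cell receptor, changed by -0.77 ± 0.040 and the interleukin 7 receptor gene IL7R by -0.48 ± 0.051. MYC, a NOTCH target with a major part in the growth of these leukemias, stood at -0.31 ± 0.10 and was not called (adjusted p = 0.280). HES4 at -1.64 ± 0.25 (adjusted p = 0.0672) and NOTCH3 at -1.26 ± 0.26 (adjusted p = 0.123) were not called either, and NOTCH1 itself stood at 0.35 ± 0.061 (adjusted p = 0.0826). Other genes named in advance that were not called were NR3C1 (0.15 ± 0.072), BCL2L11 (0.25 ± 0.068), BCL2 (0.35 ± 0.092), MCL1 (0.085 ± 0.079), TSC22D3 (-0.27 ± 0.082), FKBP5 (0.30 ± 0.056), ZBTB16 (-0.083 ± 0.25), DDIT4 (-0.0049 ± 0.072) and KLF4 (-0.13 ± 0.38).

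In all, limma called 162 genes with PF-03084014 against DMSO at a Benjamini-Hochberg adjusted p under 0.05, 93 higher and 69 lower, of which 16 and 35 differed at least 2-fold. The largest falls were in the membrane protein gene TMEM158 (-4.23 ± 0.28), the kinase gene WNK2 (-3.01 ± 0.15), the imprinted gene MEST (-2.81 ± 0.26), the scavenger receptor gene DMBT1 (-2.32 ± 0.21) and the kinase gene MAP3K8 (-2.26 ± 0.25). CHRM3-AS2 fell to the intensity floor, so its change of -2.33 was a decrease of at least that size. The chemokine receptor gene CCR2 rose from the floor by at least 3.48 (SE 0.26, adjusted p = 0.0175), and the thymic homing receptor gene CCR9 rose by 1.40 ± 0.098. Other large rises were in the pseudokinase gene TRIB1 (2.53 ± 0.21), the microtubule gene MTCL1 (2.33 ± 0.11), the immediate early gene EGR1 (1.94 ± 0.16), the hematopoietic gene HEMGN (1.72 ± 0.16), the sodium channel gene SCN3A (1.67 ± 0.17) and the kinase inhibitor gene PKIB (1.38 ± 0.12). The number of calls was unstable: it fell when an array of DMSO, PF-03084014 or dexamethasone was left out and rose without a combination array. Leaving out a dexamethasone or combination array does not alter the PF-03084014 changes themselves, whose median over all genes stayed at 0.018. It alters only the error estimate and its degrees of freedom, so these counts do not show that single arrays carried the changes. When each array was shifted to a common median, 28 genes were called and 21.4% of them were higher, against 57.4% in the main fit. The median change over all genes was 0.018 in both fits, so this count does not show that the changes themselves depended on scaling. Several fits with 1 array left out ended every call, so the calls of the 33 genes called among those named could not hold in each fit. All 33 genes kept their direction, but for the largest rises and falls the naming rule had fixed this. It required both treated arrays to lie beyond both control arrays.

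Among gene lists fixed in advance, the list of 20 NOTCH targets showed the lowest camera p-value with PF-03084014. Of its members 0 rose, 8 fell and 12 were not called, with 1 up and 12 down when adjusted over the list alone. The median was -0.68 (adjusted p = 2.66e-12, and adjusted p = 0.193 with an estimated correlation). Lists of biosynthesis, which growing cells need, lay lower without a member called over all genes. Ribosome biogenesis had a median of -0.25 (camera adjusted p = 9.68e-11), with WDR12 at -0.44 ± 0.072. Purine, pyrimidine and folate synthesis had -0.25 (2.36e-07), amino acid and polyamine metabolism -0.30 (1.80e-06) with the spermidine synthase gene SRM at -0.55 ± 0.091, and aminoacyl-tRNA synthetases -0.19 (2.20e-08) with IARS1 at -0.36 ± 0.047. Adjusted over the list alone, 7, 6, 8 and 7 members of these lists were lower, and with an estimated correlation the adjusted p-values were 0.259, 0.259, 0.368 and 0.373. Cholesterol synthesis (-0.17, camera adjusted p = 8.55e-05) and the zinc-binding metallothioneins (-0.77, 4.82e-05) were also lower, with 5 of 19 and 4 of 7 members lower when adjusted over the list alone and with adjusted p = 0.247 and adjusted p = 0.238 with an estimated correlation. Without DMSO replicate 1 the synthetase median was -0.13.

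Glycolysis genes had a median of -0.081 with PF-03084014 (camera adjusted p = 0.00139, and adjusted p = 0.529 with an estimated correlation). Of 19 members, 2 fell, ALDOC (-0.75 ± 0.082) and PFKM (-0.39 ± 0.046), and 17 were not called, and the same 2 were lower adjusted over the list alone. DNA replication and G1/S genes had a median of -0.076 (0.00726) with 0 of 30 called over the list alone, and mitochondrial respiratory chain genes -0.038 (0.0279). With an estimated correlation these became adjusted p = 0.607 and adjusted p = 0.770. Without DMSO replicate 2 the camera calls of all these lists ended, at adjusted p = 0.543, 0.131 and 0.174, with a glycolysis median of 0.0051, and the respiratory chain call also ended without PF-03084014 replicate 2, at 0.159. The DNA replication median was -0.033 without DMSO replicate 2, and without DMSO replicate 1 the glycolysis median was -0.32.

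Several lists lay higher with PF-03084014. Of 28 T cell receptor and thymocyte genes, 4 rose and 1 fell, with 13 up and 4 down adjusted over the list alone (median 0.20, camera adjusted p = 9.10e-05, and adjusted p = 0.368 with an estimated correlation). The recombinase gene RAG2 rose by 0.87 ± 0.10 and the antigen-presenting CD1C by 0.77 ± 0.090. Glucocorticoid receptor targets had a median of 0.18 (3.66e-04, and adjusted p = 0.257 with an estimated correlation) with 2 members higher, the kinase gene SGK1 (0.87 ± 0.10) and the phosphatase gene DUSP1 (0.59 ± 0.049, and -0.046 when probe sets were averaged), and 1 lower, RGS1 (-1.99 ± 0.17), and with 11 up and 2 down adjusted over the list alone. FOXO targets and quiescence genes had a median of 0.24 (0.00173, and adjusted p = 0.259 with an estimated correlation) with 10 up and 2 down adjusted over the list alone, CCNG2 among them at 0.61 ± 0.063. NF-kappaB targets (0.30, 0.0264) included LTB (0.92 ± 0.10) and CD83 (0.57 ± 0.069), and autophagy and lysosome genes (0.18, 0.00128) had 5 members higher adjusted over the list alone. With an estimated correlation these had adjusted p = 0.259 and adjusted p = 0.238, and the NF-kappaB call ended without PF-03084014 replicate 1 (0.0769), combination replicate 1 (0.0942) or combination replicate 2 (0.103). Single members of other lists that rose were the CDK inhibitor gene CDKN2D (0.76 ± 0.077), BCL2L1 (0.38 ± 0.032) and the ER degradation gene EDEM1 (0.43 ± 0.047). Without DMSO replicate 1 the NF-kappaB median was 0.14.

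**Figure D2:**
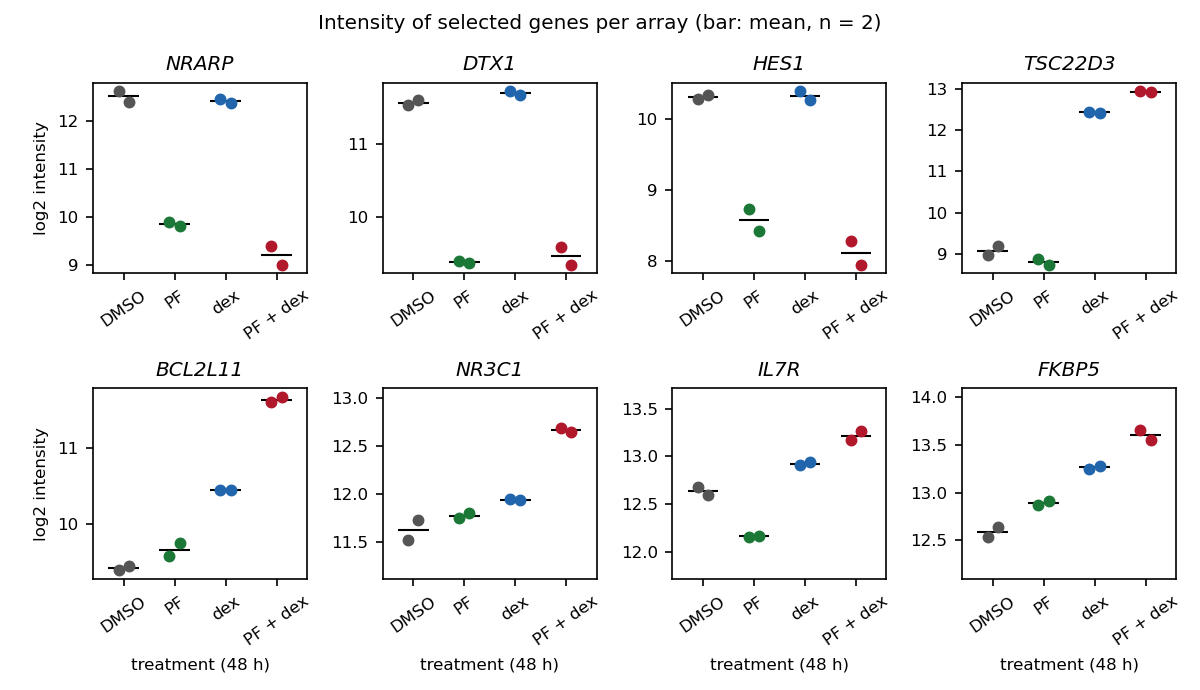
Log2 intensity of 8 genes named in advance on each array, with a bar at the mean of the 2 arrays per group (PF, PF-03084014; dex, dexamethasone). NRARP, DTX1 and HES1 were low in both groups that received PF-03084014, TSC22D3 was high in both groups that received dexamethasone, and BCL2L11 and NR3C1 were highest in the combination.

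The next comparison asked what the glucocorticoid alone changed, and some classical glucocorticoid receptor targets rose. TSC22D3, which encodes the anti-inflammatory protein GILZ, rose by 3.34 ± 0.082 log2 units (limma adjusted p = 0.00140), from 9.09 ± 0.14 to 12.43 ± 0.0089 log2 intensity (mean ± SD, n = 2). BCL2L11, which encodes the death-promoting protein BIM, rose by 1.04 ± 0.068 (adjusted p = 0.0290), but none of its 6 other probe sets was called, and the brightest of these stood at 0.17 (0.982). FKBP5, a chaperone of the receptor, rose by 0.68 ± 0.056 (adjusted p = 0.0466). The receptor gene NR3C1 stood at 0.32 ± 0.072 and was not called (adjusted p = 0.299), and IL7R stood at 0.29 ± 0.051 (adjusted p = 0.210). NRARP, DTX1 and HES1 differed from DMSO by -0.10 ± 0.14, 0.13 ± 0.083 and 0.024 ± 0.15, none of them called. Of NOTCH targets only PTCRA rose, by 0.52 ± 0.040. BCL2 at -0.087 ± 0.092, MCL1 at -0.0081 ± 0.079 and MYC at 0.066 ± 0.10 were not called. Nor were ZBTB16 (0.20 ± 0.25, adjusted p = 0.927), DDIT4 (0.22 ± 0.072, 0.466), KLF4 (-0.37 ± 0.38, 0.896), HES4 (0.0048 ± 0.25), NOTCH3 (0.70 ± 0.26) and NOTCH1 (0.045 ± 0.061).

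With dexamethasone against DMSO limma called 20 genes at a Benjamini-Hochberg adjusted p under 0.05, 17 higher and 3 lower, and 14 of the higher genes rose at least 2-fold. PFKFB2 (3.41 ± 0.14), an enzyme gene of glycolysis control, had the largest rise, followed after TSC22D3 by MACROD2 (2.92 ± 0.17), the integrin gene ITGA6 (2.08 ± 0.17), the centrosomal gene CROCC (1.79 ± 0.11) and TMT1A (1.71 ± 0.11). The exonuclease gene ISG20 rose by 1.62 ± 0.085, the histone gene H2AC6 by 1.23 ± 0.10 and the antiproliferative gene BTG1 by 1.21 ± 0.039. The falls were in dim genes. HIC1 changed by -0.997 ± 0.073, and LINC02805 and SCAT1 fell by at least 0.67 and 0.58 since both dexamethasone arrays stood at the intensity floor. Any array left out lowered the count: to 1 without DMSO replicate 1 or either PF-03084014 array, 2 without DMSO replicate 2, 0 without either dexamethasone array and 6 without either combination array. After a shift of the arrays to a common median, 2 genes were called, 100% of them higher against 85% in the main fit. Leaving out either dexamethasone array ended every call, so those of the 15 genes called among those named could not hold in all 8 fits with 1 array left out.

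Of 28 glucocorticoid receptor targets, 5 rose with dexamethasone, 0 fell and 23 were not called, with 13 up and 1 down adjusted over the list alone. The median was 0.24 (camera adjusted p = 7.36e-11, and adjusted p = 0.238 with an estimated correlation). Proliferation lists lay slightly lower: DNA replication and G1/S had a median of -0.13 (3.73e-08), with CDC45 at -0.23 ± 0.049, mitosis and G2/M -0.13 (9.34e-08), with CDK1 at -0.11 ± 0.032, and G1 cyclins, CDKs and CDK inhibitors -0.059 (0.00528), with CDK2 at -0.34 ± 0.034. No member of these was called over all genes, 0, 0 and 2 were lower adjusted over the list alone, and the lists had adjusted p = 0.340, 0.238 and 0.246 with an estimated correlation. Cholesterol synthesis had a median of -0.21 (1.58e-06, and adjusted p = 0.238 with an estimated correlation) with 6 of 19 members lower adjusted over the list alone and STARD4 at -0.59 ± 0.082. Metallothioneins (-0.51, 0.00109), amino acid and polyamine metabolism (-0.15, 4.89e-04) and glycolysis (-0.051, 0.00256) were lower too, with 2, 0 and 1 members called over the list alone and adjusted p = 0.246, 0.493 and 0.563 with an estimated correlation. The glycolysis call ended without DMSO replicate 2 (adjusted p = 0.860). Without DMSO replicate 1 or 2 the amino acid median was -0.054 or -0.27 and the glycolysis median -0.19 or -0.0023. Without dexamethasone replicate 1 or 2 the G1 median was -0.092 or -0.10.

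The list of death-promoting BCL2 family genes was higher with dexamethasone (median 0.12, camera adjusted p = 0.0182, and adjusted p = 0.257 with an estimated correlation), with 1 of 12 members, BCL2L11, called over all genes and 3 adjusted over the list alone. That call ended without DMSO replicate 1 (0.153) or combination replicate 2 (0.0512). T cell receptor and thymocyte genes (0.078, 0.0196) had 5 members up and 1 down adjusted over the list alone, and unfolded protein and integrated stress response genes (-0.084, 0.0209) had none, with adjusted p = 0.565 and 0.411 with an estimated correlation. These calls ended without DMSO replicate 1 (0.0600 and 0.350), the first also without dexamethasone replicate 1 (0.0897) and the second without dexamethasone replicate 2 (0.134). Without DMSO replicate 1 or 2 the median of the death list was 0.058 or 0.26 and that of the stress response list -0.040 or -0.14.

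The combination against DMSO asked what both compounds together changed. The glucocorticoid receptor gene NR3C1 changed by 1.05 ± 0.072 log2 units (limma adjusted p = 0.00342), from 11.62 ± 0.15 to 12.67 ± 0.034 log2 intensity (mean ± SD, n = 2), and each of its 5 probe sets was called higher. BMF, which encodes a death-promoting member of the BCL2 family, rose by 3.27 ± 0.20 and BCL2L11 by 2.23 ± 0.068 (adjusted p = 0.00110). Of the other 6 BCL2L11 probe sets 4 were called, and the 2 brightest stood at 0.72 (0.158) and 0.66 (0.176). Against dexamethasone these 2 stood at 0.54 (0.274) and 0.49 (0.299). TSC22D3 rose by 3.84 ± 0.082, FKBP5 by 1.01 ± 0.056 and IL7R by 0.58 ± 0.051, though a second IL7R probe set stood at -0.050 (adjusted p = 0.979). NRARP (-3.31 ± 0.14), DTX1 (-2.10 ± 0.083), HES1 (-2.20 ± 0.15), HES4 (-2.30 ± 0.25), HES5 (-2.55 ± 0.13) and PTCRA (-0.38 ± 0.040) fell. NOTCH1 (0.56 ± 0.061), BCL2 (0.44 ± 0.092) and BCL2L1 (0.39 ± 0.032) rose, though BCL2 stood at -0.056 when the probe sets of each gene were averaged. MYC stood at -0.24 ± 0.10 (adjusted p = 0.190), MCL1 at 0.13 ± 0.079, NOTCH3 at -0.39 ± 0.26, DDIT4 at 0.20 ± 0.072, ZBTB16 at 0.62 ± 0.25 and KLF4 at -0.27 ± 0.38, none of them called. Of the dimmer probe sets of MCL1, 2 were called higher (0.65 and 0.75, adjusted p = 0.00308 and 0.0238), the first also with PF-03084014 alone (0.52, 0.0203) and against dexamethasone (0.45, 0.0124).

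The combination changed 2360 genes against DMSO (limma, Benjamini-Hochberg adjusted p under 0.05), 1269 higher and 1091 lower, of which 209 and 239 differed at least 2-fold. With combination replicate 2 left out, the array that stood apart, 2118 genes were called, 1543 of them the same, and without combination replicate 1 the count was 6219. Leaving out DMSO replicate 1 or 2 gave 826 or 871, either PF-03084014 array 1273 or 1272 and either dexamethasone array 1175 or 1182. After a shift of the arrays to a common median, 974 genes were called, 35.5% of them higher against 53.8% in the main fit, and with array weights 859. The largest rises were in the chloride channel gene CLIC3 (at least 4.09) and CCR2 (at least 3.88), both from the floor in DMSO, TSC22D3, PFKFB2 (3.82 ± 0.14), the PI3K inhibitor gene PIK3IP1 (3.61 ± 0.30, and 1.40 and 1.07 in its other probe sets, the second not called), the adhesion gene NEGR1 (3.48 ± 0.34) and IGFBP3 (3.42 ± 0.52). The largest falls were in TMEM158, by at least 6.21 since 1 combination array stood at the floor, and in the proteoglycan gene GPC1 (-3.83 ± 0.47), ENPP1 (-3.35 ± 0.61), LINC02762 (-3.26 ± 0.49), FXYD6 (-3.11 ± 0.25), the BMP target ID1 (-3.02 ± 0.32) and the actin capping gene CAPG (-3.01 ± 0.27). Of the 74 genes called among those named, 43 were called in all 8 fits with 1 array left out. ENPP1 was called in 3 and LINC02762 in 4 of them, with changes from -3.96 to -2.74 and from -3.98 to -2.53.

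DNA replication genes fell most widely as a group. Of 30 DNA replication and G1/S genes, 22 fell with the combination, 0 rose and 8 were not called, with 27 down and 1 up adjusted over the list alone (median -0.57, camera adjusted p = 6.96e-17, and adjusted p = 0.246 with an estimated correlation). POLD1 (-1.06 ± 0.12) and GINS2 (-0.97 ± 0.11) fell most, though GINS2 stood at 0.17 when probe sets ending in _x_at or _s_at were left out. With combination replicate 2 left out the median was -0.51, with 22 members lower. Of 26 mitosis and G2/M genes 5 fell, CDC25C (-0.59 ± 0.11) and AURKA (-0.38 ± 0.070) among them, and the same number adjusted over the list alone (median -0.18, 8.42e-04, and adjusted p = 0.257 with an estimated correlation). Among G1 regulators CDKN1A (-1.82 ± 0.28) and CDK4 (-0.84 ± 0.18) fell and CCNG2 (0.57 ± 0.063) and CDKN2D (0.36 ± 0.077) rose; the median of that list was 0.015, its mean -0.18, and it was not called (0.309). The mitosis median was -0.11 without combination replicate 2.

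Metabolic lists lay lower with the combination. Of 19 glycolysis genes, 11 fell and 8 were not called, with 14 lower adjusted over the list alone (median -0.49, camera adjusted p = 5.10e-10, and adjusted p = 0.266 with an estimated correlation), led by ALDOC (-1.93 ± 0.082) and ENO2 (-1.79 ± 0.20). Of 22 purine, pyrimidine and folate genes 11 fell, 17 adjusted over the list alone (median -0.44, 7.49e-10, and adjusted p = 0.246 with an estimated correlation), including MTHFD2 (-0.74 ± 0.094). Of 19 cholesterol synthesis genes 10 fell, 12 adjusted over the list alone with 1 higher (median -0.62, 1.59e-07, and adjusted p = 0.238 with an estimated correlation), led by STARD4 (-1.27 ± 0.082) and DHCR7 (-1.20 ± 0.099). Of 20 amino acid and polyamine genes 10 fell and 1 rose, 15 and 2 adjusted over the list alone (median -0.52, 5.93e-07, and adjusted p = 0.354 with an estimated correlation), with the cystine carrier gene SLC7A11 (-1.82 ± 0.41) and ASS1 (-1.75 ± 0.13) lowest. SLC7A11 was called in 1 of 8 fits with 1 array left out, with changes from -2.46 to -1.18. Aminoacyl-tRNA synthetases (4 of 17 fell, 9 adjusted over the list alone, median -0.18, 1.59e-05) and ribosome biogenesis (3 of 30 fell, 3 adjusted over the list alone, median -0.18, 1.54e-04) were lower, BYSL (-1.19 ± 0.093) and FARSB (-0.52 ± 0.061) among them, each with adjusted p = 0.480 with an estimated correlation. Metallothioneins (3 of 7 fell, also adjusted over the list alone, median -0.75, 0.0182) and the respiratory chain (2 of 27 fell, also adjusted over the list alone, median -0.11, 0.00299) had adjusted p = 0.320 and 0.694 with an estimated correlation. The metallothionein median was 0.49 when probe sets ending in _x_at or _s_at were left out, and the call ended without combination replicate 1 (0.0743) and the respiratory chain call without combination replicate 2 (0.341), with MT2A at -1.19 ± 0.27 and SDHA at -0.31 ± 0.038. Without combination replicate 1 the synthetase median was -0.39 and the respiratory chain median -0.19. The respiratory chain and metallothionein medians were -0.033 and -0.41 without combination replicate 2.

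Of 28 glucocorticoid receptor targets 15 rose with the combination and 1, RGS1 (-1.34 ± 0.17), fell, with 16 up and 1 down adjusted over the list alone (median 0.61, camera adjusted p = 5.12e-09, and adjusted p = 0.238 with an estimated correlation). Of 20 NOTCH targets 8 fell and 2, IL7R and NOTCH1, rose, the same numbers adjusted over the list alone (median -0.29, 2.41e-04, and adjusted p = 0.238 with an estimated correlation). FOXO targets and quiescence genes had 8 members up and 2 down (9 and 2 adjusted over the list alone), led by PIK3IP1 and the glucose uptake inhibitor gene TXNIP (2.63 ± 0.21), with S1PR1 (-1.15 ± 0.18) lowest (median 0.24, 0.00890, and adjusted p = 0.329 with an estimated correlation). The T-cell list had 8 members up and 1 down (9 and 2 adjusted over the list alone), led by the recombinase genes RAG1 (1.84 ± 0.16) and RAG2 (1.39 ± 0.10) (median 0.12, 0.0279, and adjusted p = 0.589 with an estimated correlation). With combination replicate 2 left out the FOXO call ended (0.0510), and without combination replicate 1 the T-cell call ended (0.573). With arrays shifted to a common median the T-cell list stood at -0.011 and was not called (0.190). The median of the BCL2 family death list was -0.16 although its mean was 0.47, with BMF and BCL2L11 up and PMAIP1 (-0.52 ± 0.061) down, and it was not called (0.704). Of stress response genes XBP1 (1.07 ± 0.11) rose and HSP90B1 (-2.03 ± 0.45) fell, of interferon genes IFIT2 (1.07 ± 0.15) rose and IFIT1 (-1.81 ± 0.23) fell, and the autophagy kinase gene ULK1 (0.87 ± 0.13) rose, in lists that were not called. Without combination replicate 1 the NOTCH target median was -0.18, and without combination replicate 1 or 2 the T-cell median was 0.061 or 0.18.

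**Figure D3:**
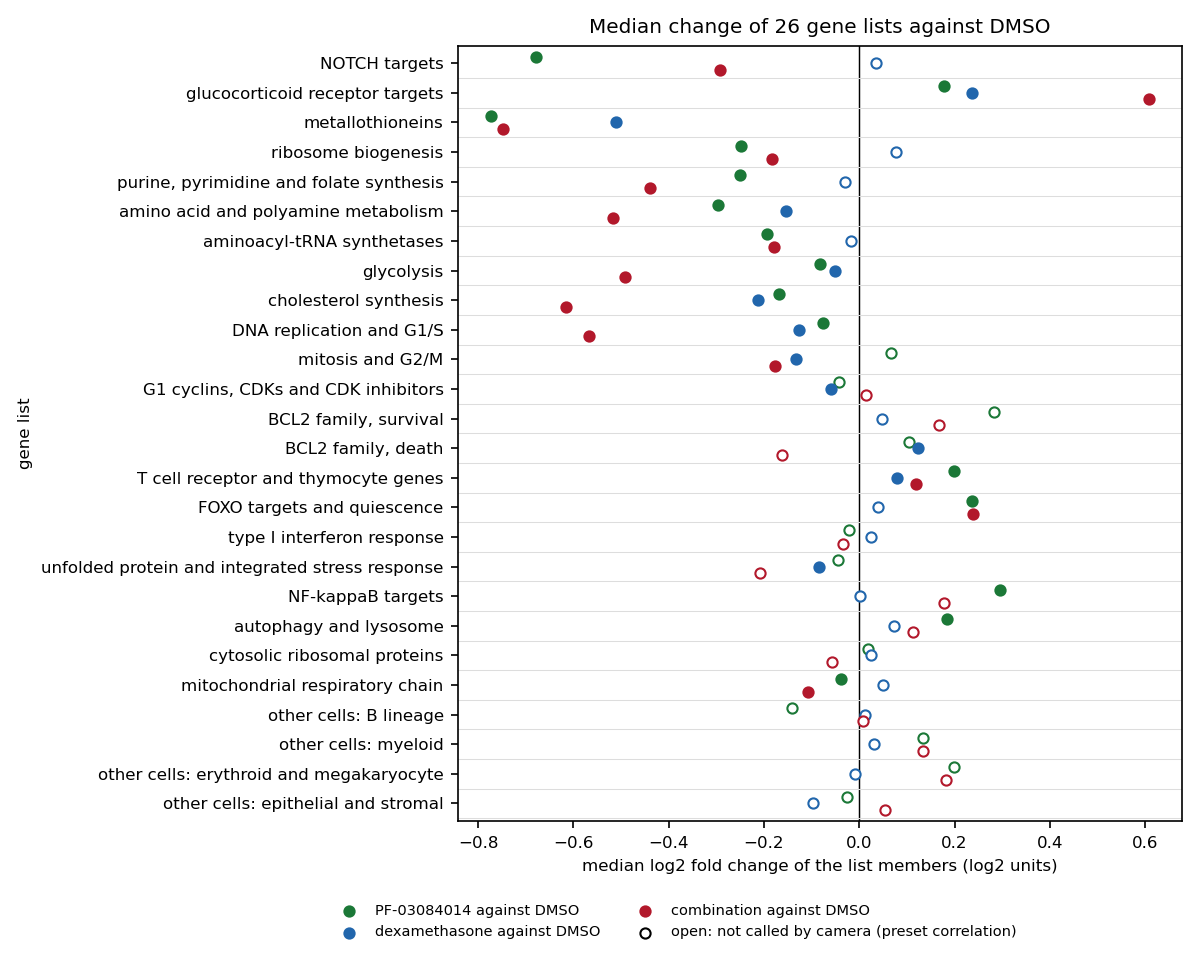
Median log2 fold change of the members of 26 gene lists for each treatment against DMSO, filled where camera with its preset correlation had an adjusted p under 0.05. The median of DNA replication genes was -0.57 with the combination against -0.076 with PF-03084014 and -0.13 with dexamethasone, and the median of glucocorticoid receptor targets was highest with the combination (0.61).

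The combination against dexamethasone asked what NOTCH inhibition added to the glucocorticoid. NR3C1 rose by 0.73 ± 0.072 (limma adjusted p = 0.0138), BCL2L11 by 1.19 ± 0.068 (adjusted p = 0.00602), TSC22D3 by 0.50 ± 0.082, FKBP5 by 0.34 ± 0.056, SGK1 by 1.00 ± 0.10 and BMF by 1.05 ± 0.20. Of the 5 NR3C1 probe sets 3 were called higher, and the 2 dimmest stood at 0.83 and 0.85 without a call. With combination replicate 2 left out the NR3C1 difference was 0.76. IL7R rose by 0.29 ± 0.051, opposite to its fall with PF-03084014 alone, but stood at 0.0099 when probe sets were averaged. NRARP (-3.21 ± 0.14), DTX1 (-2.23 ± 0.083), HES1 (-2.23 ± 0.15), HES4 (-2.31 ± 0.25), HES5 (-2.63 ± 0.13) and PTCRA (-0.90 ± 0.040) fell, MYC stood at -0.31 ± 0.10 (adjusted p = 0.135) and NOTCH3 at -1.08 ± 0.26 (adjusted p = 0.0761). NOTCH1 rose by 0.51 ± 0.061 and BCL2 by 0.52 ± 0.092, while MCL1 (0.14 ± 0.079), ZBTB16 (0.42 ± 0.25), DDIT4 (-0.014 ± 0.072) and KLF4 (0.10 ± 0.38) were not called. The largest rises were in CCR2 (at least 3.58), IGFBP3 (3.13 ± 0.52), TEX55 (at least 2.42), NEGR1 (2.31 ± 0.34) and MTCL1 (2.17 ± 0.11), where for CCR2 and TEX55 1 dexamethasone array stood at the floor. The largest fall was in TMEM158, at -5.17 or lower since 1 combination array stood at the floor. Further large falls were in GPC1 (-3.61 ± 0.47), BMP4 (-3.10 ± 0.33) and WNK2 (-3.05 ± 0.15). The calls of the 62 genes called among those named could not hold in all 8 fits with 1 array left out. Leaving out either dexamethasone array ended every call of this contrast, so this says nothing about these genes.

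Limma called 1430 genes in this comparison at a Benjamini-Hochberg adjusted p under 0.05, 645 higher and 785 lower. With array weights, which allow for the larger spread of the combination arrays, 191 were called. Leaving out either dexamethasone array left 0 genes, either PF-03084014 array 340 or 339, DMSO replicate 1 or 2 673 or 677, and combination replicate 1 gave 5826. Shifting the arrays to a common median moved the median of all genes from 0.041 to -0.066 and left 305 genes, 20.3% of them higher against 45.1% in the main fit. Of 28 glucocorticoid receptor targets 11 rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.37, camera adjusted p = 1.72e-05, and adjusted p = 0.246 with an estimated correlation). NOTCH targets had 8 members down and 2 up, 10 and 2 adjusted over the list alone (median -0.34, 1.14e-04, and adjusted p = 0.238 with an estimated correlation). DNA replication had 18 of 30 members down, 22 adjusted over the list alone (median -0.40, 8.33e-14), glycolysis 9 of 19, 14 adjusted over the list alone (-0.41, 3.39e-09), and purine synthesis 9 of 22, 16 adjusted over the list alone (-0.44, 1.58e-09), PFAS among them at -0.53 ± 0.094. With an estimated correlation these had adjusted p = 0.249, 0.289 and 0.246. The NOTCH target median was -0.51 without combination replicate 2.

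Further lists lay lower in the combination than in dexamethasone. Ribosome biogenesis had a median of -0.25 with 5 members down, BYSL (-1.08 ± 0.093) lowest (camera adjusted p = 6.09e-07, and adjusted p = 0.368 with an estimated correlation). Cholesterol synthesis had 7 of 19 members down, SQLE (-0.68 ± 0.093) and DHCR7 (-0.79 ± 0.099) among them (median -0.46, 2.67e-05, and adjusted p = 0.246 with an estimated correlation). Amino acid metabolism (-0.43, 4.82e-05), aminoacyl-tRNA synthetases (-0.19, 9.72e-05) and the respiratory chain (-0.17, 3.92e-05) had 6, 4 and 3 members down, ASS1 at -1.10 ± 0.13 and NDUFV1 at -0.32 ± 0.060, with adjusted p = 0.453, 0.517 and 0.575 with an estimated correlation. Adjusted over the list alone, 8, 10, 12, 7 and 8 members of these lists, in the order named, were lower. FOXO targets had 5 members up, 10 adjusted over the list alone, CCNG2 (0.52 ± 0.063) among them (median 0.27, 0.00340, and adjusted p = 0.279 with an estimated correlation). Cytosolic ribosomal proteins (-0.074, 0.0196, and adjusted p = 0.775 with an estimated correlation) were called lower with no member called, and that call ended without dexamethasone replicate 2 (0.0540) and without combination replicate 2 (0.659), where the median was 0.014. Leaving out combination replicate 2, the medians were -0.10 for the synthetases, -0.068 for the respiratory chain and 0.17 for FOXO targets. Without combination replicate 1 that of the ribosomal proteins was -0.16.

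The combination against PF-03084014 asked what the glucocorticoid added to NOTCH inhibition. PFKFB2 (4.47 ± 0.14), TSC22D3 (4.10 ± 0.082), CLIC3 (3.59 ± 0.43), LINC01120 (2.83 ± 0.23) and the sialyltransferase gene ST3GAL6 (2.82 ± 0.29) rose most (limma adjusted p between 4.64e-04 and 0.0269). The other, dimmer LINC01120 probe set stood at -1.20 and was not called (limma adjusted p = 0.477). BMF (2.69 ± 0.20), BCL2L11 (1.98 ± 0.068), BTG1 (1.37 ± 0.039), IL7R (1.06 ± 0.051), NR3C1 (0.90 ± 0.072) and FKBP5 (0.71 ± 0.056) rose as well. The NOTCH targets NRARP (-0.65 ± 0.14), DTX1 (0.086 ± 0.083) and HES1 (-0.47 ± 0.15) were not called. A second, dimmer HES1 probe set was called lower, at -0.82 (limma adjusted p = 0.0354). PTCRA rose by 0.39 ± 0.040, though a second probe set stood at -0.13 (adjusted p = 0.879). HES4 (-0.67 ± 0.25), NOTCH3 (0.87 ± 0.26), NOTCH1 (0.20 ± 0.061), MYC (0.067 ± 0.10), BCL2 (0.085 ± 0.092), MCL1 (0.049 ± 0.079), ZBTB16 (0.70 ± 0.25), DDIT4 (0.21 ± 0.072) and KLF4 (-0.14 ± 0.38) were not called. The largest falls were in SLC25A53 (-2.45 or lower), FXYD6 (-2.03 ± 0.25), TMEM158 (-1.99 or lower), the transcription factor gene MAF (-1.82 ± 0.21) and FHL2 (-1.73 ± 0.28), with 1 combination array at the floor for SLC25A53 and TMEM158. The other, dimmer SLC25A53 probe set stood at -0.25 and was not called (limma adjusted p = 0.728). In all 562 genes were called at a Benjamini-Hochberg adjusted p under 0.05, 215 higher and 347 lower. With array weights, which allow for the larger spread of the combination arrays, 18 were called. Leaving out DMSO replicate 1 or 2 left 112 or 116, either PF-03084014 array 10 or 8 and either dexamethasone array 11, and leaving out combination replicate 1 gave 3911. Of the 41 genes called among those named, 4 were called in all 8 fits with 1 array left out.

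Of 28 glucocorticoid receptor targets 9 rose, 15 adjusted over the list alone, when dexamethasone was added to PF-03084014 (median 0.44, camera adjusted p = 4.87e-08, and adjusted p = 0.238 with an estimated correlation). Of 30 DNA replication genes 16 fell, 28 adjusted over the list alone, CCNE1 (-0.79 ± 0.068) and POLD1 (-0.83 ± 0.12) among them (median -0.50, 1.93e-21, and adjusted p = 0.238 with an estimated correlation). Mitosis and G2/M had 3 of 26 members down, 11 adjusted over the list alone, with BUB1 at -0.34 ± 0.043 (median -0.20, 9.42e-08, and adjusted p = 0.238 with an estimated correlation). Glycolysis had 8 of 19 members down (-0.38, 4.64e-10), cholesterol synthesis 6 of 19 (-0.53, 1.08e-06), purine synthesis 3 of 22 (-0.17, 1.49e-05) and amino acid metabolism 2 of 20 (-0.27, 8.22e-04), with 13, 11, 6 and 3 adjusted over the list alone. With an estimated correlation these had adjusted p = 0.266, 0.238, 0.329 and 0.502. G1 regulators were lower (-0.14, 0.00890, and adjusted p = 0.246 with an estimated correlation) with CDK2 down (-0.58 ± 0.034), a call that ended without combination replicate 1 (0.124). Cytosolic ribosomal proteins (-0.071, 0.0322) and the respiratory chain (-0.069, 0.0478) were called lower without a called member, with adjusted p = 0.785 and 0.775 with an estimated correlation. Without combination replicate 2 both medians were above 0, at 0.013 and 0.011, and leaving out PF-03084014 replicate 1 ended both calls as well (0.142 and 0.203). The respiratory chain call also ended without DMSO replicate 1 (0.0600), DMSO replicate 2 (0.0592) or either dexamethasone array (0.0573). Without combination replicate 1 the medians were -0.30 for purine synthesis, -0.095 for G1 regulators, -0.14 for ribosomal proteins and -0.13 for the respiratory chain. Leaving out combination replicate 2, they were -0.12 for amino acid metabolism and -0.22 for G1 regulators, and without PF-03084014 replicate 1 -0.097 for purine synthesis.

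The interaction asked whether the effects of both compounds added up on the log2 scale. The rise of BCL2L11 with the combination exceeded the sum of the separate changes by 0.94 ± 0.096 (adjusted p = 0.306), that of IL7R by 0.77 ± 0.073 (0.306), that of TSC22D3 by 0.76 ± 0.12 (0.319) and that of NR3C1 by 0.58 ± 0.10 (0.319), and none of these was called. Limma called 0 of 19775 genes at a Benjamini-Hochberg adjusted p under 0.05, although 1792 had an unadjusted p below that level. With array weights the count was also 0. A shift of the arrays to a common median moved the median of all genes from 0 to -0.137. All 30 members of the DNA replication and G1/S list lay below the sum of the separate effects (median -0.32, camera adjusted p = 1.46e-14, and adjusted p = 0.246 with an estimated correlation), with 15 of them called over the list alone and RFC5 at -0.51 ± 0.051. Glycolysis had a median of -0.33 with 7 members lower adjusted over the list alone (1.62e-07, and adjusted p = 0.346 with an estimated correlation), TPI1 among them at -0.34 ± 0.065. Without combination replicate 2 the DNA replication and glycolysis medians were -0.24 (1.03e-12) and -0.28 (1.50e-05).

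**Figure D4:**
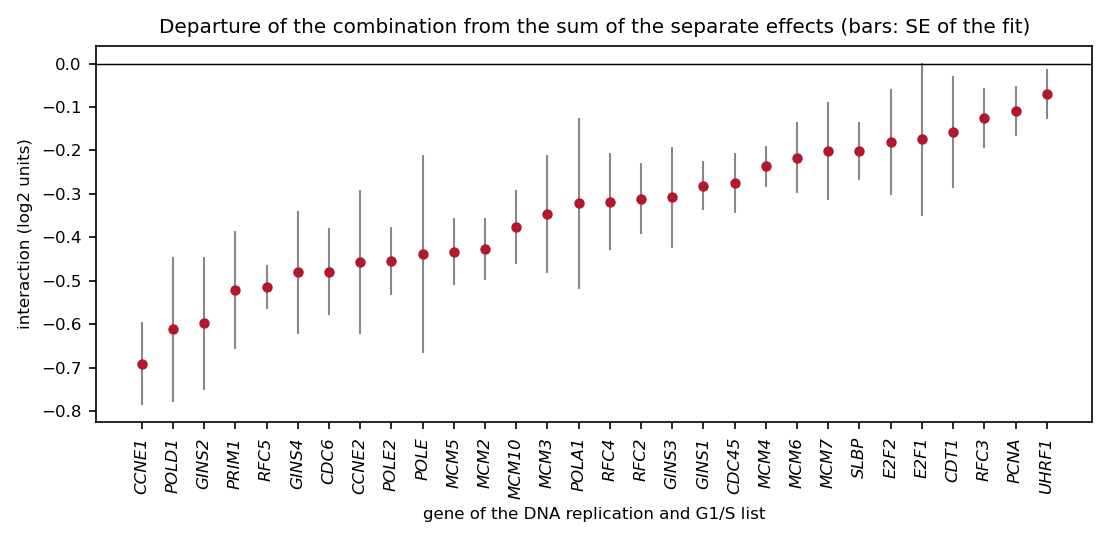
Departure of the combination from the sum of the separate effects (log2 units) for each of the 30 DNA replication and G1/S genes, with bars of 1 standard error from the fit. Every point lies below 0 and the median is -0.32.

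Other lists called in the interaction were purine synthesis (-0.16, camera adjusted p = 3.78e-04), the respiratory chain (-0.12, 0.00486), cytosolic ribosomal proteins (-0.089, 0.0209) and cholesterol synthesis (-0.21, 0.0481), all below the sum, and metallothioneins (0.49, 0.00340) and glucocorticoid receptor targets (0.080, 0.0395), above it. With the arrays shifted, when the median of all genes was -0.137, the glucocorticoid target median was -0.017 and not called (0.345). With an estimated correlation these had, in the same order, adjusted p = 0.411, 0.717, 0.775, 0.480, 0.257 and 0.462. Of 28 glucocorticoid receptor targets only 15 lay above the sum, called or not. Adjusted over the list alone, 3 glucocorticoid receptor targets lay above the sum and 1 below it, and no member of the other lists of this group was called. Without combination replicate 2 the respiratory chain (0.586), ribosomal protein (0.802) and cholesterol (0.121) calls ended. The ribosomal protein call also ended without DMSO replicate 1 (0.0983), PF-03084014 replicate 1 (0.0904) or dexamethasone replicate 2 (0.0555). The cholesterol call ended without DMSO replicate 1 (0.251), PF-03084014 replicate 1 (0.166) or 2 (0.0573), or dexamethasone replicate 1 (0.130) or 2 (0.0685). The glucocorticoid target call ended without DMSO replicate 2 (0.237), PF-03084014 replicate 1 (0.0671), dexamethasone replicate 1 (0.0880) or 2 (0.0719), or combination replicate 1 (0.355), and the metallothionein call without combination replicate 1 (0.0981). Without combination replicate 1 or 2 the medians were -0.26 or -0.10 for purine synthesis, -0.19 or -0.036 for the respiratory chain and -0.18 or -0.0096 for ribosomal proteins. The cholesterol median was -0.13 without DMSO replicate 1 and -0.14 without combination replicate 2, and that of glucocorticoid targets 0.0086 without DMSO replicate 2 and 0.044 without PF-03084014 replicate 1.

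Genes called with PF-03084014 alone were mostly called with it on top of dexamethasone too. Of the 93 genes that rose with PF-03084014 alone, 84 also rose between dexamethasone and the combination, where 3.03 would overlap by chance, and of the 69 that fell, 60 also fell, where 2.74 would. The chance counts given here take the calls as independent, although all contrasts use the same error estimate of each gene. IL7R was the only gene called in opposite directions, -0.48 and 0.29. The call against dexamethasone held in 1 of 8 fits with an array left out, and a second IL7R probe set stood at -0.27 there, not called (adjusted p = 0.641). Across genes, which are not independent replicates, the log2 changes of these array sets without a shared array correlated with r = 0.394 over 19775 genes and 0.658 over the 10692 genes with a mean intensity above 100. All 17 genes that rose with dexamethasone alone also rose between PF-03084014 and the combination (0.185 by chance). None of the 3 that fell did so there (0.053 by chance), where at least 1 PF-03084014 array already stood at the floor. The changes correlated with r = 0.205 over all genes and 0.469 over those above 100.

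**Figure D5:**
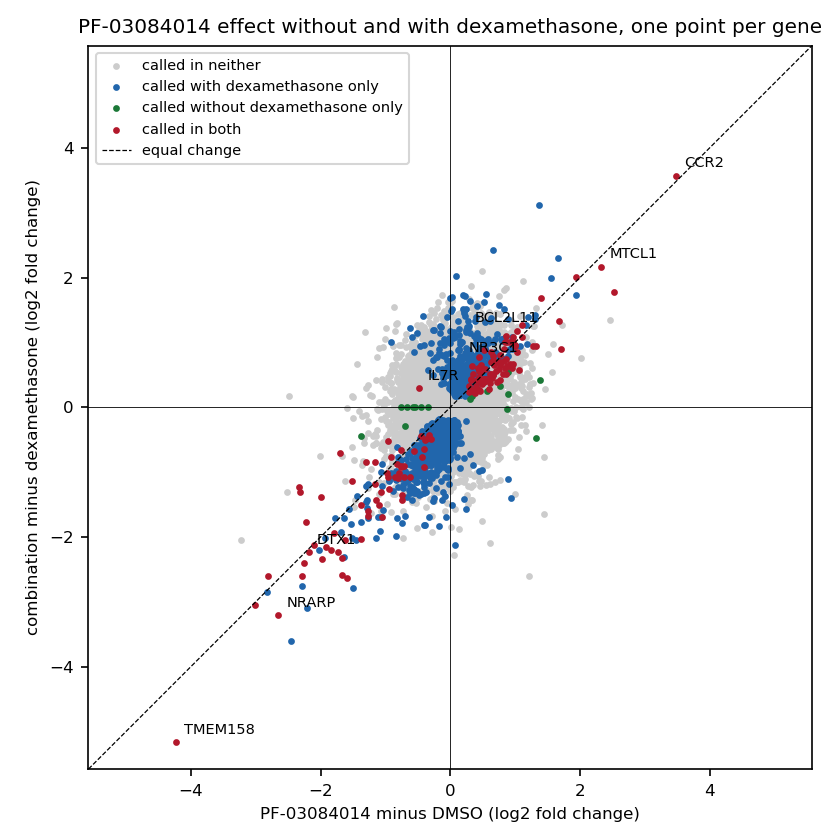
Log2 fold change of each of 19775 genes with PF-03084014 against DMSO (horizontal) and with the combination against dexamethasone (vertical), coloured by limma calls at an adjusted p under 0.05, with a dashed line of equal change. TMEM158, NRARP and DTX1 lie low on both axes and CCR2 high on both, while BCL2L11 and NR3C1 lie above the line.

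PF-03084014 and dexamethasone, each against DMSO, shared 2 rises (0.080 by chance), H2AC6 and TMT1A, and 3 falls (0.010 by chance), HIC1, LINC02805 and SCAT1. These names outside the naming rule were chosen after their values were seen. These chance counts take the contrasts as independent although both use the DMSO arrays, and simulated unchanged groups, which shared 0 calls, give no expected overlap for groups that changed. The falls were in dim genes with at least 1 PF-03084014 array at the floor, and for the last 2 also both dexamethasone arrays. These falls may lie within background. H2AC6 rose by 0.86 ± 0.10 with PF-03084014 and 1.23 ± 0.10 with dexamethasone, and TMT1A by 0.89 ± 0.11 and 1.71 ± 0.11. PTCRA was called in opposite directions, -0.77 and 0.52. The shared DMSO arrays alone gave r = 0.4998 across genes in 20 simulations of unchanged groups, above the observed 0.394. The covariance went the other way, at 0.0366 observed against 0.0314 simulated. The simulated groups lacked treatment changes, which widen the spread of the observed values, so the 2 values of r cannot decide whether the compounds act alike. The main effects of the compounds in the factorial design correlated with r = 0.373 over all genes and 0.463 over those above 100. Since the spread differed between groups, chance values in common can add to these. The overlap fell to between 0 and 1 genes whenever any 1 array was left out.

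Lists that camera did not call in any comparison were survival genes of the BCL2 family (median 0.28 with PF-03084014, 0.048 with dexamethasone and 0.17 with the combination, each against DMSO) and the type I interferon response (-0.022, 0.025 and -0.034). Markers of other cells, listed to look for foreign signal, were not called either: the medians with the combination were 0.0088 for the B lineage, 0.13 for myeloid, 0.18 for erythroid and megakaryocyte and 0.053 for epithelial and stromal markers. Single members that changed with the combination were the B-lineage gene CD79A (0.86 ± 0.090) and the myeloid integrin gene ITGAM (-1.72 ± 0.17). Median, mean and test direction differed in sign for the G1 list with PF-03084014 (median -0.042, mean 0.0021, direction up), and for NF-kappaB targets with dexamethasone the median was 0.0016 and the mean -0.019. Against DMSO with the combination, the test direction was down for the B lineage (mean 0.077), myeloid (mean 0.039) and epithelial (mean 0.039) lists although median and mean lay above 0, and with dexamethasone it was down for the myeloid list (median 0.031, mean 0.073). The signs also differed in the other comparisons for lists that were not called, giving 19 of 156 list and comparison pairs in all.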

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

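The lists below were fixed before the data were examined, and the tests of explanations were chosen after the results were seen. In 8 gene lists the effect of PF-03084014 differed between cells without and with dexamethasone, by limma's camera test of the interaction with its preset correlation. These were DNA replication and G1/S (adjusted p = 1.46e-14), glycolysis (1.62e-07), purine, pyrimidine and folate synthesis (3.78e-04), metallothioneins (0.00340), the mitochondrial respiratory chain (0.00486), cytosolic ribosomal proteins (0.0209), glucocorticoid receptor targets (0.0395) and cholesterol synthesis (0.0481). With an estimated correlation none was called, and the lowest adjusted p was 0.246. Camera calls of 3 lists held whichever array was left out. After quantile normalization the medians of the respiratory chain (-0.063, adjusted p = 0.106), ribosomal proteins (-0.011, 0.826) and cholesterol synthesis (-0.15, 0.208) lay closer to 0 and were not called. With arrays shifted to 1 median the first 2 stayed called (-0.27, 0.0105 and -0.24, 0.0300), cholesterol synthesis was not called (-0.35, 0.0544) and glucocorticoid receptor targets stood at -0.017 (0.345), so the part of array scaling in these lists was left open.

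The first pattern weighed was that all 30 DNA replication genes lay below the sum of the separate effects. Had the second combination array carried this, the median without it would have been near 0, and it was -0.24. Unequal array scaling was likewise not borne out, since quantile normalization left a median of -0.27. A biological hypothesis was a smaller share of cycling cells, taken to lower DNA replication and mitosis genes alike. The medians of these lists differed by -0.23 (permutation test over 100000 gene reassignments, two-sided p = 1.00e-05, the smallest they can give). That test treats genes as replicates although they are not independent, and it presumes equal log2 shifts in both lists. It therefore cannot exclude this hypothesis. A block before S phase was not tested and remains open.

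The second pattern weighed was the rise of NR3C1 between dexamethasone and the combination, in a receptor gene known for inducing itself in T-cell leukemia. Without the second combination array the rise was 0.76, so that array did not carry it. The hypothesis that NOTCH inhibition raises NR3C1 by itself, for instance through the fall of HES1, was tested in cells without dexamethasone. There NR3C1 stood at 0.15 ± 0.072 and its upper 95% limit, 0.33, lay below the 0.37 that makes up 0.5 of the rise against dexamethasone. With that bound taken as fixed, PF-03084014 alone gave less than 0.5 of the rise, but a smaller part was not excluded. The interaction of this gene was not called (0.58 ± 0.10, limma adjusted p = 0.319), so a need for the glucocorticoid was not shown.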

How the results depend on the processing

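A floor of 64, a minimum mean intensity of 100 and quantile normalization without the second combination array were added after the values were seen, the other settings before. Over all settings, 11 list values and 12 named-gene values called in either fit reversed (for lists, the direction of the test), and 185 and 83 more changed direction without a call in either. A median can change sign where the test direction does not, as in glucocorticoid receptor targets in the interaction with arrays shifted (-0.017) and glycolysis with PF-03084014 without DMSO replicate 2 (0.0051). Intensity over background and 2 arrays per group limit all calls. Calls of many named genes were lost with 1 array left out. All 33 called genes for PF-03084014 and all 15 for dexamethasone kept their direction. The naming rule had fixed this for the largest rises and falls, so it is no separate evidence for them. With the correlation between genes estimated, the NOTCH target list with PF-03084014 (median -0.68) and the glucocorticoid receptor target list with dexamethasone (0.24) were no longer called (adjusted p = 0.193 and 0.238); the test then also refers to 4 degrees of freedom. With 1 array left out, the NOTCH target median ranged from -0.73 to -0.62 and the glucocorticoid target median from 0.23 to 0.29.

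Counts of called genes follow for PF-03084014, dexamethasone and the combination against DMSO (main 162, 20 and 2360), the combination against dexamethasone (1430) and against PF-03084014 (562), and the interaction (0), and only values that moved by over 1.5 times are given, except for robust estimation and the replicate block. Leaving out 1 array gave 0 to 354, 0 to 6, 826 to 6219, 0 to 5826, 8 to 3911 and 0 to 1016, with a group of 1 array assumed to vary like the others. With only the 2 groups compared in the fit, and 2 residual degrees of freedom, the first 5 were 0. Robust estimation moved none by that much (228, 28, 2588, 1628, 581 and 0). Quantile normalization gave 11 for dexamethasone. Arrays shifted to 1 median gave 28, 2, 974, 305 and 131. A floor of 32 gave 42 for dexamethasone and 11 for the interaction, a floor of 64 gave 9 for the interaction, and a pseudocount of 16 gave 318 and 56. Without the genes below the median intensity the counts were 433, 59, 2395 against dexamethasone and 960 against PF-03084014, and with a mean intensity over 100 416, 59, 2364 and 944. The mean of probe sets gave 93, 8, 787 and 285, and no _x_at or _s_at probe sets gave 11 for dexamethasone, 947 against dexamethasone and 1 for the interaction. No trend gave 69, 10, 904 and 260. Array weights, which were 0.315 for both combination arrays, gave 728, 109, 859, 191 and 18. Quantile normalization without the second combination array gave 261, 5 and 901 against dexamethasone. The replicate block, checked because the groups share replicate numbers, gave 76, 3, 2277, 1294, 380 and 0, and differences between replicates correlated between groups by only -0.010 to 0.082, so arrays were not paired. Except where stated, the cause was not tested.

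The correlation across genes of the PF-03084014 effect without and with dexamethasone (main 0.394) was 0.692 without the genes below the median intensity and 0.319 to 0.384 with 1 array left out. That of the dexamethasone effect (main 0.205) was 0.503 and 0.114 to 0.260. The overlap of both compounds (main 5) was 3 after quantile normalization, 0 with arrays shifted, 23 without the dimmer genes, 2 with the mean of probe sets, 3 without _x_at and _s_at probe sets, 0 with the replicate block and 0 to 1 with 1 array left out. The cause was not tested.

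Medians of lists whose test direction reversed follow. Cytosolic ribosomal proteins in the combination against PF-03084014 stood at 0.011 after quantile normalization, -0.0063 with the mean of probe sets, -0.014 without _x_at and _s_at probe sets, 0.023 with quantile normalization and no second combination array, and between -0.14 and 0.013 with 1 array left out, the highest without the second combination array. With 1 array left out the same list ranged from -0.16 to 0.014 against dexamethasone and from -0.18 to -0.0096 in the interaction, again highest without that array, and with quantile normalization added the interaction median was 0.0016. The respiratory chain against PF-03084014 ranged from -0.13 to 0.011, highest without that array, and stood at 0.0022 without it and with quantile normalization added. Metallothioneins in the combination against DMSO stood at 0.49 without _x_at and _s_at probe sets. With the mean of probe sets, DUSP1 with PF-03084014 was -0.046, BCL2 and SHMT1 in the combination against DMSO -0.056 and 0.0023, and POLR1B and CDK2 in the combination against dexamethasone 0.038 and 0.063. Without _x_at and _s_at probe sets, MT1G, SHMT1, YARS1 and GINS2 in the combination against DMSO were 0.69, 1.12, 0.063 and 0.17, and PAICS, GINS2 and KLF2 against dexamethasone 0.95, 0.20 and -0.11. The last settings replace the probe set of a gene by others, and the cause was not tested.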

Other observations

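The genes and tests of this part were chosen after the results were seen. The BMP signalling gene BMP4 stood at -2.22 ± 0.33 with PF-03084014 alone (limma adjusted p = 0.0651) and fell by 2.68 with the combination against DMSO, and its target ID1 stood at -2.29 ± 0.32 (adjusted p = 0.0568) and fell by 3.02. These were single genes, not a list fixed in advance. The related gene ID3 stood at 0.33 ± 0.12 with PF-03084014 (adjusted p = 0.314) and changed by -0.63 ± 0.12 with the combination, each against DMSO. With PF-03084014, FOS rose by 1.11 ± 0.094, the phosphatase gene DUSP6 by 0.44 ± 0.045 and EGR1 by 1.94 ± 0.16, while KLF4 stood at -0.13 ± 0.38 and was not called, and FOS rose by 1.41 ± 0.094 with the combination.

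A further pattern was that many more genes were called with the combination (2360) than with either compound (162 and 20). Without the second combination array the count was 2118 against 353 for both single compounds together, and with quantile normalization added 1988 against 266, but the lone combination array was then assumed to vary like the others, so a part of that array in these calls was left open. With array weights, which allow for the larger spread of the combination arrays, the counts were 859 and 837, so much of the pattern may come from 1 spread pooled over groups that vary unequally. Effects beyond the sum of both compounds could not be told from an addition of smaller effects that each stayed uncalled, as 0 genes were called in the interaction.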
